A study of Mus musculus with 4 samples.

How the data were processed

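Gene expression was measured in a stable NIH3T3 line, an immortalised mouse fibroblast line, that carries wild-type PKR behind a promoter silenced by tetracycline. Per the labels, cells were kept in 1 µg/ml tetracycline with 5% serum, or had tetracycline withdrawn for 5 h to switch PKR on. The serum content is not given for the withdrawn cultures. Total RNA was measured on 4 arrays of 2 types. Each condition has 1 array of each type, and the second type is marked MB in the sample titles. The types carry different probe sets, so the arrays of a condition are not replicates and were never averaged per probe set. Whether the 2 arrays of a condition came from the same RNA is not stated.

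The deposited tables hold 1 linear intensity per probe set and array, with no detection calls. The probe set and control names follow the Affymetrix scheme. No label or file header names the software, and the steps from scan to table are not given in the sources used here. All values were above 0. The 2% trimmed mean of the non-control probe sets was 1000 and 1000.4 on the first array type and 997 on both arrays of the MB type, as in tables already scaled to a common mean, though no label records that step. The deposited intensities were used without further scaling, by a rule that kept deposited values where these means lay within 5% of each other.

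Control probe sets (61 per array type: Affymetrix controls and yeast genes) stayed out of all counts and lists, which left 6523 probe sets on the first type and 6534 on the MB type. Gene names came from a platform annotation, with symbols updated through Entrez identifiers. On the first type 5541 probe sets had 1 symbol, 197 had several and 785 had none. On the MB type these numbers were 2001, 27 and 4506. Of the probe sets with 1 symbol, 5532 and 1993 matched the RefSeq gene table of GRCm38.p6. No probe set with several symbols was named, and unnamed probe sets entered the counts only. The files name no genome build, so no coordinates are given.

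A probe set was called measured when its intensity exceeded a floor, the 25th percentile of the pooled values of an array type (130 on the first type, 80.0 on the MB type). A second floor was added after the data were examined. It is the 95th percentile of the 39 bacterial and yeast control probe sets, pooled over the 2 arrays of a type (281.5 and 340.4), and is called the control floor. The change is log2 of the withdrawn over the tetracycline intensity, with no pseudocount. With 1 array per condition no p-value was computed. A difference was counted when it reached 2-fold between values both above the floor. A probe set above the floor on 1 array only has a bound, the bright intensity over the floor. The same bound against the control floor was added after the data were examined, since control probe sets exceeded the main floor. For some named changes the spread is given, a robust SD (scaled median absolute deviation) of the changes of the 200 probe sets nearest in level. It holds probe noise and real differences together and is no replicate error.

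The 30 gene lists were written before the data were examined, as were the gene naming rule, the floor rule and the alternatives except those named here as later additions. A gene took the median change over its measured probe sets on both array types. A list with at least 5 measured genes was described by its median and by that median's percentile among 10000 random lists of the same size, matched on level in 10 bins. Such a percentile describes these arrays only. Named are Eif2ak2, the 8 largest changes and the 3 largest bounds per array type and direction among probe sets with 1 symbol, and up to 4 members of each list past 2-fold. The rule for the 8 largest changes was repeated at the control floor, and that repeat was chosen after the data were examined.

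The counting of probe sets was tested on simulated arrays with known answers, whose noise was normal with the observed spread. Of 200 probe sets well above the floor that were changed by 2-fold, 54.5% were counted on the first type and 48.5% on the MB type. At 3-fold these shares were 90.0% and 91.5%, and at 4-fold 98.5% and 99.0%. The list percentile was tested on gene changes drawn independently from 1 normal distribution (SD 0.4 on the log2 scale), not on simulated arrays. In these draws a list shifted by 0.5 on the log2 scale lay at percentile 100. Of 40 unshifted lists, 0 fell outside the middle 95%. Genes of a real list may vary together, which these draws do not cover. Alternatives were other scalings (2% trimmed mean, quantile, median ratio, loess with a span of 0.4), a lower floor (64.9 and 40.0) and a higher floor (259 and 160), 1.5-fold and 3-fold limits, genes in place of probe sets, the brightest probe set per gene, and each array type alone. Removing from 2 lists the genes that other lists hold was added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.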

Results

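The data set compares NIH3T3 fibroblasts in which wild-type PKR was kept silent by tetracycline with the same line 5 h after tetracycline was withdrawn. PKR, encoded by Eif2ak2, is a kinase activated by double-stranded RNA that phosphorylates the translation initiation factor eIF2 alpha. The comparison addresses which transcripts differ in abundance when PKR is induced. Each condition was measured on 1 array of each of 2 types, with 6523 and 6534 probe sets after removal of controls. No difference therefore has a replicate check, and all changes describe these 4 arrays. The number of arrays limits the precision. On the first type 76.0% of probe sets exceeded the floor with tetracycline and 74.0% after withdrawal, and on the MB type 74.3% and 75.7%. Intensities of the 2 conditions correlated across probe sets with a Spearman rho of 0.92 on the first type and 0.89 on the MB type. Probe sets are not independent replicates. The ratio of the 3' to the 5' control probe set, a measure of RNA integrity, lay between 0.93 and 1.05 for beta-actin and between 0.71 and 0.83 for Gapdh on the 4 arrays.

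The induced gene was examined first. The only probe set named Eif2ak2, on the first array type, read 643.3 with tetracycline and 663.6 after withdrawal. Its log2 change of 0.045 was small against the spread of 0.50 among probe sets of similar level. The labels do not give the species of the PKR transgene, and the mouse probe set may not detect its transcript, so this value does not check the labels.

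The 8 largest upward differences of each array type above the control floor included those of Klf10, Gadd45a, Gadd45b, Trib3, Ppp1r15a and Nfkbia. These were picked from the rankings after their values were seen, and the full rankings are given below. They also hold 2610005L07Rik (1.98), Sod3 (1.78) and Slc4a1 (1.58), among others. For Sod3 and Slc4a1 a probe set on the other array type went the other way. Klf10, a transcription factor induced early by TGF-beta, was 5.68-fold higher (504.1 to 2864.3). Gadd45a and Gadd45b, stress-induced regulators of growth arrest and MAP kinase signalling, were 4.75-fold (775.1 to 3678.1) and 4.05-fold higher (3163.1 to 12825.6). Trib3, a pseudokinase induced by ATF4, was 4.32-fold higher, and Ppp1r15a, the phosphatase subunit that reverses eIF2 alpha phosphorylation, 2.93-fold. Both probe sets of Nfkbia, the NF-kB inhibitor I kappa B alpha, were higher, with log2 changes of 1.28 and 1.34. Tnfaip3, encoding the NF-kB feedback inhibitor A20, read 10.8 with tetracycline, below the floor, and 901.4 after withdrawal. Its bound was 2.65-fold against the control floor and 11.3-fold against the main floor. On the same arrays the bacterial BioDn 3' control read 263.8 with tetracycline and 1212.8 after withdrawal. The bound for this single probe set therefore does not exclude background signal. For comparison, the spread at the level of these probe sets was 0.40 for Klf10, 0.38 for Gadd45a, 0.29 for Gadd45b, 0.48 for Trib3 and 0.29 for Ppp1r15a on the log2 scale.

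**Figure D1:**
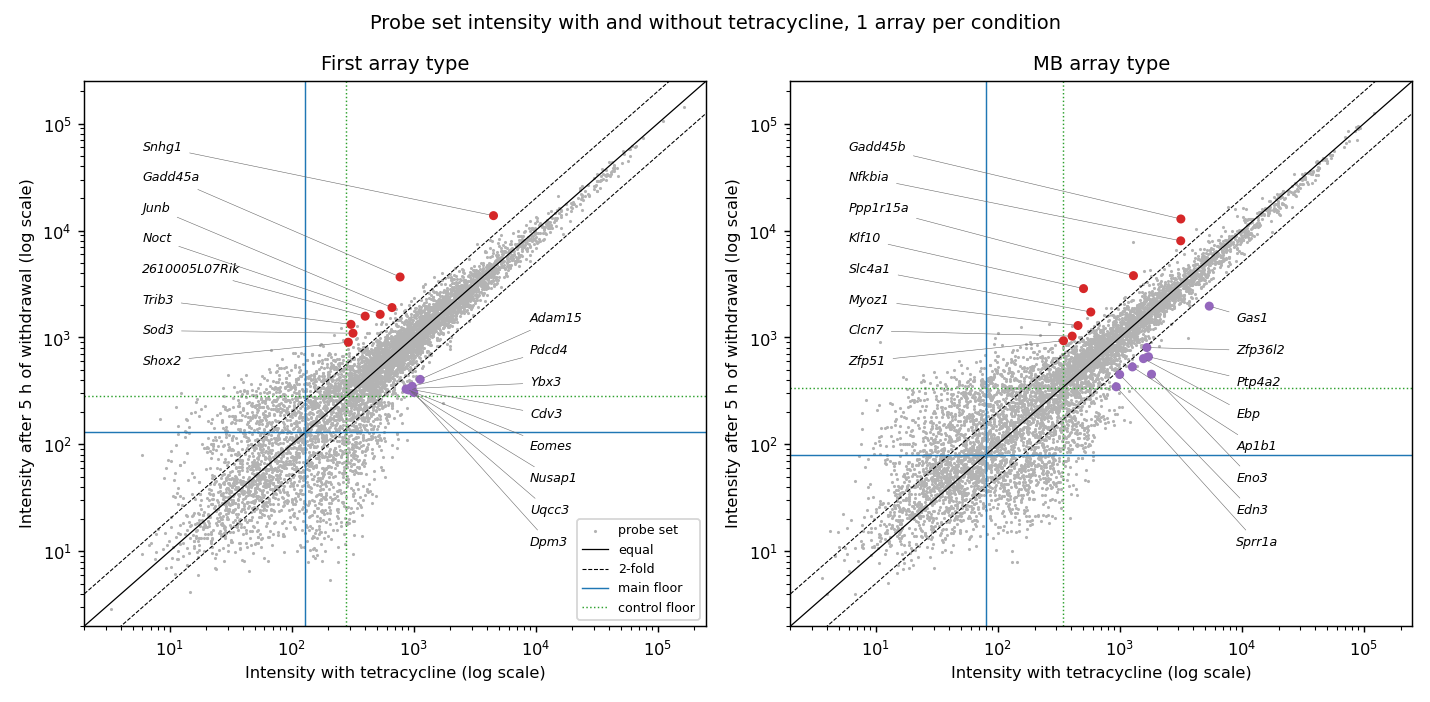
Intensity of each probe set after 5 h of withdrawal (vertical, log scale) against that with tetracycline (horizontal, log scale), with the 2 array types in separate panels and 1 array per condition. Lines mark equality, 2-fold differences, the main floor (130 and 80.0) and the control floor (281.5 and 340.4). Labelled are the 8 largest changes per direction above the control floor, with Klf10 at 504.1 and 2864.3.

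Of the fixed lists, immediate early genes, the transcription factors and signalling regulators switched on within minutes of a stimulus, had the highest median. Of 32 measured members, 29 were higher after withdrawal to any extent, 8 of them by at least 2-fold, and none was lower by 2-fold. The median log2 change was 0.72, above all 10000 random lists, whose middle 95% spanned -0.15 to 0.16. Named members were Klf10 (2.51), Klf2 (1.63, below the control floor with tetracycline), the AP-1 subunit Junb (1.52) and Klf4 (1.44). The list median was 0.72 on the first array type alone and 0.43 on the MB type alone. Serum is such a stimulus, and the labels give a serum content for the tetracycline cultures only.

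Integrated stress response genes, which are transcribed when eIF2 alpha is phosphorylated, were higher in 22 of 26 measured members, 5 of them by at least 2-fold and none lower by 2-fold. Their median log2 change was 0.39, above all random lists, with 0.26 on the first array type alone and 0.75 on the MB type alone. Trib3 (2.11), Ppp1r15a (1.55), the endoplasmic reticulum protein gene Herpud1 (1.25) and the transcription factor Cebpg (1.08) had the largest changes, followed by Atf3 (1.01). Ddit3, which encodes CHOP, read 2292.7 with tetracycline and 4357.3 after withdrawal (log2 change 0.93), and Atf4, the transcription factor upstream of many of these genes, 10151.2 and 13494.4 (0.41). Ddit3 and Atf4 were chosen after their values were seen. So were Shmt2 (-0.57), Psat1 (-0.29), Phgdh (-0.10) and Xpot (-0.087), which were lower. Without the genes that other lists also hold, the median was 0.33 for the stress response list and 0.66 for the immediate early list, both above all random lists. The unfolded protein response list, which shares Herpud1, had a median of -0.11 over 14 members, within the range of random lists (percentile 24.4), and below it with the brightest probe set per gene (-0.25, percentile 1.96).

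NF-kB target genes went both ways. Of 35 measured members, 6 were higher by at least 2-fold, 2 were lower, and 23 were higher to any extent. Gadd45b (2.02), the inhibitor Nfkbib (1.82) and the apoptosis inhibitor Birc2 (2.80-fold) were higher. Nos2, which encodes inducible nitric oxide synthase (-1.42), and the adhesion molecule Icam1 (-1.25) were the 2 lower ones. Nfkbib, Birc2 and Nos2 were each below the control floor on 1 array, and Icam1 on both. Above the control floor 4 of 26 members were higher by 2-fold and none was lower: Gadd45b, the NF-kB subunit Relb (1.36), Nfkbia (1.31) and Tnfaip2 (1.23). Abundant members, chosen after their values were seen, were the chemokines Ccl2 (0.26) and Cxcl1 (0.42) and the adhesion molecule Vcam1 (0.037). The list median of 0.14 lay at the upper edge of the middle 95% of random lists (-0.20 to 0.14) and inside it under every alternative run, down to percentile 91.1 on the MB type alone.

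In 4 lists the median lay below the middle 95% of random lists. S phase genes had a median of -0.32, with 21 of 29 members lower and percentile 0. The replication licensing gene Cdc6 was 1 of these (-2.30), but was below the control floor after withdrawal (491.9 to 99.7). Others, chosen after their values were seen, were the replicative helicase gene Mcm6, with -1.34 and -0.29 on 2 probe sets, and Pcna (-0.33). Antioxidant genes had a median of -0.30 (percentile 0.03), with 18 of 25 members lower and the glutathione transferase Gsta4 at -1.25. Extracellular matrix genes had a median of -0.24 (percentile 0.17), with 28 of 36 members lower, Fbln1 at -1.67 (201.9 after withdrawal, below the control floor) and the elastin gene Eln, chosen after its values were seen, higher on both its probe sets (1.21 and 0.73). Of 3 probe sets of the collagen Col1a1, chosen likewise, 2 were lower (both -0.36) and 1 was higher (0.33). Respiratory chain genes had a median of -0.18 (percentile 0.83), with 42 of 55 members lower and none by 2-fold. On the MB type alone the antioxidant and respiratory chain lists lay inside the middle 95%, at percentiles 8.59 and 27.5, as did the matrix list on either type alone (3.25 and 3.31). Of the 26 lists with a percentile, 7 lay outside the middle 95%, NF-kB targets included. By chance 1.3 would, if genes of a list varied as independently as randomly drawn genes, which was not tested.

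**Figure D2:**
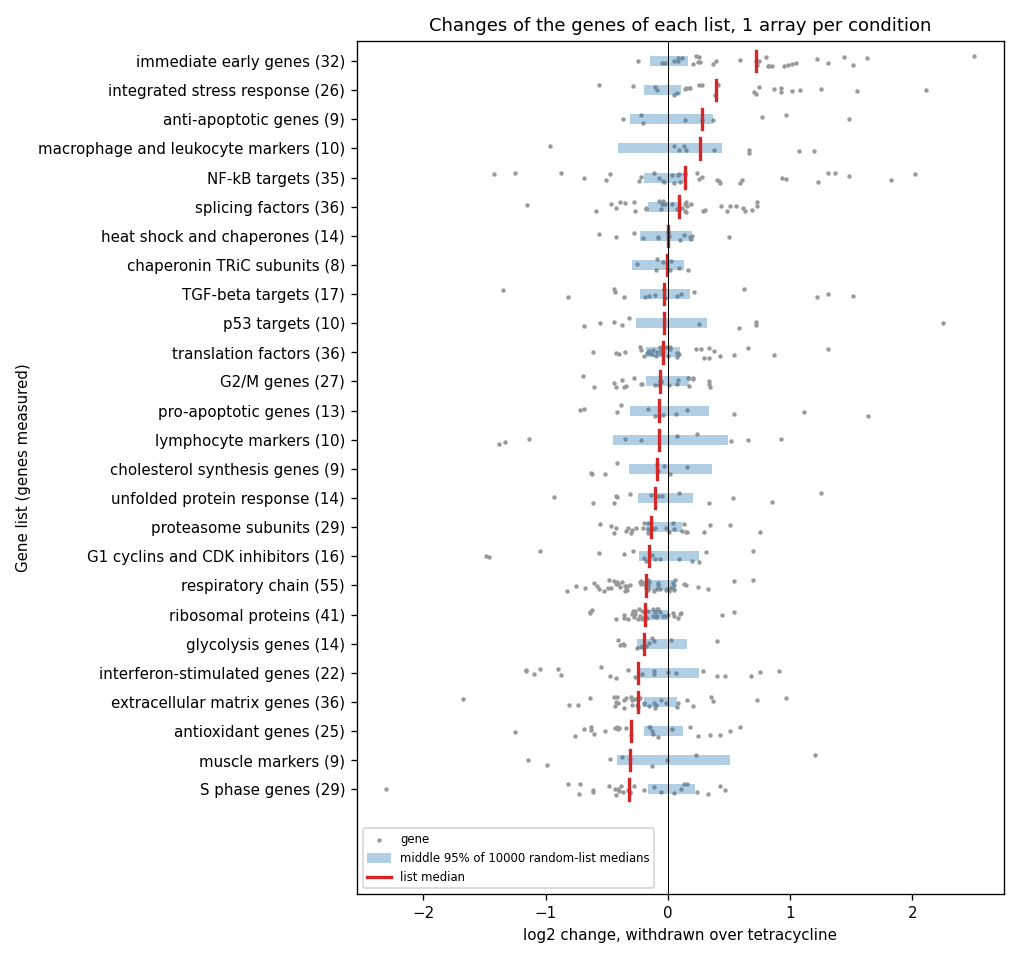
Log2 change (withdrawn over tetracycline) of the measured genes of each list (grey points, number in parentheses), with the list median (red) and the middle 95% of medians of 10000 matched random lists (blue). The immediate early (0.72) and integrated stress response (0.39) medians lie above their random ranges, and the S phase (-0.32), antioxidant (-0.30) and extracellular matrix (-0.24) medians below.

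The remaining lists lay within the middle 95%. Interferon-stimulated genes had a median of -0.24 (percentile 3.19), with 4 of 22 members lower by 2-fold and none higher: Lgals3bp (-1.16), the signalling inhibitor Socs1 (-1.16), the transcription factor Irf8 (-1.09) and Gbp2 (-1.05). Lgals3bp and Gbp2 were below the control floor after withdrawal, and the list lay at percentile 1.10 with the brightest probe set per gene, but on the MB type alone its median was above 0 (0.19, percentile 76.7). Pro-apoptotic genes had a median of -0.070 over 13 members, with Casp4 (1.64) and Bcl2l11 (1.12) higher but both below the control floor with tetracycline. Anti-apoptotic genes had a median of 0.28 over 9 members (percentile 91.5), with Birc2 past 2-fold. Among p53 targets only Gadd45a of 10 measured genes passed 2-fold (2.25), and the list median was -0.029 with a mean of 0.21, and 0.26 at the control floor. The G1 list held the growth arrest gene Gas1, lower from 5407.3 to 1964 (-1.46), and the pocket protein genes Rbl1 (-1.49) and Rbl2 (-1.05) among 16 members with a median of -0.15, with Rbl1 and Rbl2 below the control floor after withdrawal. TGF-beta targets had a median of -0.029 over 17 members, with Junb, Smad3 (1.31) and Id1 higher and Tgfbi (-1.35) lower, of which Smad3 and Tgfbi were below the control floor on 1 array. Both Id1 probe sets were higher, with 1.95 on the first type, from below the control floor, and 0.48 on the MB type. Medians of the G2/M (-0.064), heat shock (0.0038), glycolysis (-0.20), cholesterol synthesis (-0.089) and proteasome (-0.14) lists rested on 27, 14, 14, 9 and 29 genes, none past 2-fold. Cholesterol synthesis genes had a median of -0.31 at the control floor, at percentile 2.02, and glycolysis genes one of -0.26 with the brightest probe set per gene, at percentile 1.74. Ribosomal protein genes had a median of -0.19 over 41 genes (percentile 3.29). It lay below the middle 95% on the first type alone (-0.20, percentile 1.545) and at the lower floor (percentile 2.20), and inside it on the MB type alone (-0.092, percentile 73.2) and with quantile normalization (-0.028, percentile 63.4). Splicing factor genes had a median of 0.091 over 36 genes, with Snrpa1 (-1.15) past 2-fold. Medians of the 36 translation factor genes (-0.036, with Eif4h at 1.31) and the 8 TRiC chaperonin genes (-0.010) turned positive with quantile normalization and with the level trend removed. Eif4h and Snrpa1 were below the control floor on 1 array. Median and mean differed in sign for heat shock (mean -0.024), pro-apoptotic (0.072), p53 (0.21), TGF-beta (0.069), translation factor (0.064) and endothelial genes (median 0.48, mean -0.32).

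Markers of other cell types went both ways. Macrophage and leukocyte markers had a median of 0.26 over 10 genes (percentile 87.9), 9 of them higher, with Coro1a (1.20) and Fcgr3 (1.07) past 2-fold. The only lower one was the pan-leukocyte gene Ptprc, looked up after its values were seen (-0.96). Lymphocyte markers had a median of -0.075 over 10 genes, 5 of them lower, with Ighm (-1.38), Cd3g (-1.33) and Cd79b (-1.13) past 2-fold. Muscle markers had a median of -0.31 over 9 genes (percentile 6.35), 7 of them lower, with Tnnt2 (1.20) and Chrna1 (-1.14). Adipocyte (median -0.33) and epithelial markers (-0.51, with the keratin Krt14 at 1.15) had 4 measured genes each. Endothelial markers (with Tie1 at -2.16) had 3. The list written for core histones held 3 measured genes, the linker histone genes H1f5, H1f6 and H1f10 (median 0.35). It therefore describes no core histone. All these lists have too few genes for a percentile. Each marker named here past 2-fold was below the control floor on at least 1 array.

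Across the first array type, 192 probe sets were at least 2-fold higher after withdrawal and 177 at least 2-fold lower, of 4402 measured on both arrays. Above the control floor these numbers were 67 and 46 of 3555. In 20 simulated array pairs with the observed spread and no change, a median of 4630 were measured at the main floor. Of these, 113 to 172 were higher and 124 to 163 lower. At the control floor, with 3572 measured, 27 to 48 were higher and 27 to 48 lower. More probe sets were measured in the simulation than on the arrays, so the counts do not compare directly. The simulated noise was normal, and its spread holds any real differences too. The 8 largest upward differences above the control floor were Gadd45a, Trib3, 2610005L07Rik (log2 change 1.98), the extracellular superoxide dismutase Sod3 (1.78), Shox2 (1.63), Noct, which encodes the circadian protein nocturnin (1.63), the snoRNA host transcript Snhg1 (1.61, 4515.8 to 13781.6) and Junb. The largest downward differences were Dpm3 (-1.71), Uqcc3 (-1.50), Ybx3 (-1.49), Adam15 (-1.48), the translation inhibitor Pdcd4 (-1.48), Nusap1 (-1.48), Cdv3 (-1.46) and Eomes (-1.40). A probe set of Sod3 on the MB type went the other way (-0.41), and a second Cdv3 probe set on the first type gave only -0.28.

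At the main floor the largest upward differences on the first type were Lclat1 (2.31), Zfp651 (2.30), Slk (2.25), Ngef (2.25), Gadd45a (2.25), the clock gene Cry1 (2.24), Cant1 (2.23) and H2-Aa (2.22). The largest downward ones were Rangrf (-2.83), Gfra3 (-2.34), Parp16 (-2.04), Adgrb1 (-2.04), Coq10a (-1.97), Flt3 (-1.96), Mef2b (-1.86) and Padi2 (-1.85). Of these 16, only Gadd45a was above the control floor on both arrays. Their spread ranged from 0.38 for Gadd45a to 0.84 for H2-Aa. A second probe set of Zfp651 on this type (-0.056) and that of Flt3 on the MB type (0.13) had the opposite direction. Further H2-Aa probe sets gave -1.09 on this type and -0.14 and 0.73 on the MB type, and a second Gfra3 probe set read 406.7 and 405.5. Second probe sets of Rangrf (-0.36) and Cant1 (0.70) on this type gave smaller changes in the same direction. Among probe sets under the floor on 1 array, the bounds against the control floor and, in parentheses, the main floor were 2.73-fold (5.92) for the SMAD corepressor gene Skil, 2.57-fold (5.57) for Akap8 and 2.55-fold (5.54) for Brca2, all higher, and 3.12-fold (6.77) for Cd52, 2.65-fold (5.76) for Fuca1 and 2.61-fold (5.65) for Kcnj11, all lower.

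On the MB type, 369 probe sets were higher and 290 lower of 4360 measured on both arrays, and 54 and 21 of 2738 above the control floor. Simulated pairs with no change gave 241 to 293 higher and 252 to 301 lower of a median of 4722 measured at the main floor. At the control floor, with 2761 measured, they gave 11 to 25 higher and 11 to 23 lower. Here too more probe sets were measured in the simulation, so the counts do not compare directly. The excess of higher probe sets at the main floor turned with quantile normalization, to 320 higher and 333 lower, and with the level trend removed, to 323 and 334. The 8 largest upward differences above the control floor were Klf10, Gadd45b, the anion exchanger Slc4a1 (1.58), Ppp1r15a, Myoz1 (1.51), Zfp51 (1.43), Nfkbia and Clcn7 (1.34). The largest downward differences were the muscle enolase Eno3 (4.01-fold lower), Gas1 (-1.46), Sprr1a (-1.44), Ptp4a2 (-1.38), the sterol isomerase Ebp (-1.30), Ap1b1 (-1.26), Edn3 (-1.15) and Zfp36l2 (-1.05). Probe sets of Slc4a1 (-0.29), Ptp4a2 (0.078), Ap1b1 (0.22) and Zfp36l2 (0.045) on the first type, and a second Edn3 probe set on the MB type (2.25), had the opposite direction.

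At the main floor the largest upward differences on the MB type were H2-DMb1 (2.98), Ccl1 (2.70), Mcpt4 (2.52), Klf10, Bcan (2.48), Napb (2.41), Nog (2.39) and Hoxa11 (2.32). The largest downward ones were Prkcd (-2.92), Pxmp2 (-2.68), Cfp (-2.49), Serpinb9 (-2.41), Cdc6 (-2.30), Ighm (-2.30 on this probe set), Il1r2 (-2.28) and Ckb (-2.28), and the Ckb probe set of the first type was higher (1.76). Only Klf10 of these 16 was above the control floor on both arrays. Second probe sets on the MB type gave smaller changes in the same direction for Mcpt4 (1.19), Napb (0.72) and Prkcd (-0.69). So did probe sets of Serpinb9 (-0.48) and Ighm (-0.47) on the first type. Bounds given in the same way were, besides Tnfaip3, 1.99-fold (8.49) for Sstr4 and 1.73-fold (7.38) for Clcn3, both higher, and 1.54-fold (6.54) for Fzd8, 1.53-fold (6.52) for Bmp6 and 1.43-fold (6.09) for Gas8, all lower.

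Genes with probe sets on both array types were measured a second time by different probes. Of 241 such genes, 137 (56.8%) had the same sign on both types, where unrelated values would match in sign as often as not, and the changes correlated across genes with a Pearson r of 0.12 and a Spearman rho of 0.17. Genes are not independent replicates. Of the 38 genes past 2-fold on at least 1 type, 16 had the same direction on the other. The 3 genes past 2-fold in the same direction on both, which this count singles out, were Rgs16 (1.41 and 1.59), Pcyt1a (1.37 and 1.54) and Stx3 (-1.24 and -1.38). Each was below the control floor on 1 array of both types, and a second Stx3 probe set on the first type, under the main floor with tetracycline, went the other way (59.3 to 309.5). Above the control floor 8 genes were past 2-fold on at least 1 type, 2 of them had the same sign on the other, and none was past 2-fold in the same direction on both. Agreement was also low within an array type. All probe sets of a gene had the same sign in 236 of 414 genes (57.0%) on the first type. On the MB type this held for 74 of 141 genes (52.5%). Of genes past 2-fold on at least 1 probe set, 2 of 53 and 3 of 28 were past it on all, in the same direction.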

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

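The control floor used here was chosen after the data were seen. Control probe sets enter no count or list. The bacterial and yeast ones set the control floor, so some exceed it by construction. Of 122 control values per condition over both array types, 8 exceeded the control floor after withdrawal and were at least 2-fold above the tetracycline array, and 7 exceeded it with tetracycline and were at least 2-fold lower after withdrawal. On the first type, where the control floor is 281.5, the BioB 5' st control read 389.1 after withdrawal and 59.5 with tetracycline. Here st is the suffix of the probe set name. In the same order, the beta-actin 3' st control read 695.2 and 68.8. The Gapdh 3' and 5' st controls read 1081.3 and 272.7, and 342.8 and 100.1. The MA and MB pyruvate carboxylase controls read 301.7 and 130, and 336 and 161.6. On the MB type, where the control floor is 340.4, the bacterial BioDn 3' control read 1212.8 after withdrawal and 263.8 with tetracycline, and the 18S RNA 5' control 375.1 and 120.1. For the 7 that went the other way, the value after withdrawal is given last. On the first type they were BioDn 3' (447.5 and 222.3), PheX 3' (313.7 and 49.7), 18S RNA 3' (655.9 and 177.5) and the Gapdh middle st control (626.1 and 248.1). On the MB type they were BioB 5' st (391.8 and 99.7), the Gapdh middle st control (393.3 and 122.3) and the transferrin receptor 5' control (413.6 and 35.9).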

How the results depend on the processing

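No paired analysis was possible because the groups share only replicate number 1, and no array could be left out because each condition has 1 array of each type. Scaling as deposited coincided with the scaling used, and a list with under 5 measured genes on an array type gave no value there. The control floor and the removal of genes shared between lists were chosen after seeing the data. Counts of probe sets depended mainly on the floor and the limit. On the first array type, 368 were higher and 368 lower at the lower floor, 71 and 50 at the higher floor, 67 and 46 at the control floor, 545 and 471 at 1.5-fold, and 46 and 29 at 3-fold. On the MB type these pairs were 619 and 534, 165 and 108, 54 and 21, 769 and 561, and 136 and 122, and counting genes gave 100 and 77. The 4 other scalings kept every count within 1.5 times. Of the 100 named probe sets, 97 were measured with quantile normalization, 99 with loess and all with the other 2 scalings, and none of those measured changed direction or moved by more than 0.14 (log2). The scalings themselves differ little, so they could hardly turn a change past 2-fold. The floor mattered more: 50 of the named probe sets were measured at the higher floor and 44 at the control floor. Of the list medians under alternatives, 232 moved by less than the SD of the random medians and 21 by more, and the 7 lists outside the random range had the same sign in every setting run. The immediate early, integrated stress response and S phase lists stayed outside it in every setting run. The medians that moved by more were extracellular matrix with quantile normalization (-0.17), ribosomal proteins with quantile normalization (-0.028) and loess (-0.038), p53 targets (0.26) and cholesterol synthesis (-0.31) at the higher floor and at the control floor, and unfolded protein response (-0.25) and cholesterol synthesis (-0.31) with the brightest probe set. On the first type alone the integrated stress response (0.26) and G2/M (0.041) medians moved. On the MB type alone moved interferon-stimulated (0.19), integrated stress response (0.75), unfolded protein response (-0.26), heat shock (-0.12), anti-apoptotic (-0.0029), immediate early (0.43), G2/M (-0.22), ribosomal protein (-0.092), proteasome (0.010) and splicing factor (-0.051) medians. These rest on 5 to 14 genes. The cause of the other moves was not tested. The signal over background limits what low probe sets show: bacterial and yeast controls reached 447.5 on the first type and 1212.8 on the MB type.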

Other observations

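The lookups of clock genes, host transcripts and Xbp1 and the tests of explanations below were chosen after the results were seen, while each array type alone and removal of the level trend were settings fixed before. Clock-related transcripts were looked up after the values of Noct and Cry1 were seen. Per1, Noct and Cry1 were higher, and Clock and Bhlhe40 differed little. Log2 changes were 1.08 and, from below the control floor, 1.28 for Per1, 1.63 and 1.17 for Noct, 2.24 for Cry1 (also from below the control floor), 0.19 and -0.043 for Clock and -0.033 for Bhlhe40. Transcripts that host small nucleolar RNAs were also higher in 4 of 5 genes, with Snhg1 at 1.61, Snhg6 at 1.07, Snhg11 at 0.96, Gas5 at 0.60 and 0.66 on 2 probe sets, and Snhg9 at -0.10. Xbp1, a transcription factor of the unfolded protein response, went from 2337.8 to 4210.3 (0.85) while the median of that list was -0.11.

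Host transcripts such as Gas5 are degraded in a manner that depends on translation, so slower translation after PKR induction is a candidate explanation for the higher Snhg1 level. The 4 other host transcripts had a median of 0.80, and 4 genes are too few for a percentile. They were noticed before they were tested, and higher transcription predicts the same difference, so the data leave this open.

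The immediate early and integrated stress response lists were higher together. The lowest of the 4 percentiles of the 2 lists on each array type alone was 99.91. The lists were picked for their high medians over these same probe sets, so this is no independent test. Noise at the level of single probe sets therefore stays open. With the level trend removed both lists stayed at percentile 100. The random lists were matched on level, so a level trend moves them too and this percentile cannot test it. The medians were then 0.69 for the immediate early and 0.47 for the integrated stress response list, so the trend removed does not account for them. A medium change or handling at withdrawal, a difference in serum, or another difference between the cultures, cannot be told apart from PKR induction, since 0 of the 4 arrays come from cells without the transgene. PKR induction stays among the open explanations, as a hypothesis.

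The S phase, extracellular matrix, antioxidant and respiratory chain lists were lower. On an array type alone the higher percentile of S phase genes was 1.32, and the highest of the other lists was 27.49. S phase genes were set apart after the results were seen, and the same probe sets had picked the lists. Probe-level noise therefore stays open for all 4 lists. With the level trend removed the highest percentile of the 4 lists was 0.505, but matching on level keeps this from testing a level bias. The medians were then -0.32 (S phase), -0.20 (matrix), -0.31 (antioxidant) and -0.14 (respiratory chain). All stayed below 0, so the trend removed is not their whole cause. Scaling that shifts all probe sets of an array alike cannot be tested by these percentiles, since it moves a list and its random lists together. PKR induction, another difference between the cultures, and a rise of most other transcripts, which scaling would turn into lower values here, stay open and were not tested.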
